A study of Mus musculus with 4 samples.

How the data were processed

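RNA from the stomach corpus, the acid-secreting body of the stomach, was sequenced in 4 C57BL/6 wild-type mice aged 6 to 8 weeks. Per the labels, 2 mice belonged to the vehicle group and 2 received a single intraperitoneal dose of HDT, 5 mg per 20 g of body weight, and each library came from 1 mouse at 48 hr. HDT is the usual abbreviation of high-dose tamoxifen in work on gastric injury, although the labels give the abbreviation alone. The sample titles call the control group vehicle, while the protocol and design texts speak of untreated mice, so whether the controls received an injection is open. Per the labels' protocols, RNA was purified on RNeasy columns with DNase digestion and sent to BGI for library preparation and sequencing.

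Per the submitters' processing notes, STAR 2.7.1a, featureCounts, Subread 2.0.0 and edgeR were used, with the builds GRCm38 and mm10. The order of these tools, the gene annotation, the strand setting and the normalization method are not given in the sources used here. The deposited table holds 52125 rows named by gene symbol and 4 library columns, and 23219 rows are 0 in every library. Its values are a signal in the sense of normalized gene counts: each value the authors deposited is a whole number of reads multiplied by a factor that is constant within a library. The worth of 1 read was 1.1381 in vehicle replicate 1, 1.12 in vehicle replicate 2, 1.1192 in HDT replicate 1 and 1.1128 in HDT replicate 2. Dividing by it gave whole reads for 100% of the values above 0 in every library, within the 0.01 that rounding to 2 decimals allows. The recovered depth was 41536686, 42104568, 42175023 and 42674985 reads in the same order. Spreadsheet conversion had turned 26 symbols into dates, of which 2 occur on 2 rows each, and these 4 rows were kept apart. GENCODE release M21, on GRCm38, holds 47608 of the symbols and supplied gene positions, and Dpcr1 is not a symbol in that release.

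The test fixed before the data were examined was edgeR's quasi-likelihood test on counts. Because the table holds normalized values, limma took its place as the main test and the count test on recovered reads became an added alternative. Genes were kept by edgeR's filterByExpr on the recovered reads, which left 18285 genes, each with at least 10 reads in its highest library. The deposited values were divided by effective library sizes, column totals times TMM factors, with factors of 0.848, 0.818, 1.219 and 1.183 for vehicle replicates 1 and 2 and HDT replicates 1 and 2. They were then transformed as log2(value + 1), where the pseudocount of 1 corresponds to 0.89 reads. A fold change is therefore on the log2(value + pseudocount) scale, which understates the change of genes with few reads. HDT was compared with vehicle by limma with a mean-variance trend and robust moderation, with group as the only term. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The adjusted p-values measure an effect against the spread between 2 mice per group, moderated towards the trend over genes. The median prior degrees of freedom were 5.88, so much of each spread estimate was borrowed from other genes. Levels are given as CPM, from the recovered reads and the TMM-scaled library size, as mean ± SD over 2 mice.

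Before the data were examined, 46 gene lists were fixed for cell types and pathways, 12 of them as primary lists. Each list was tested with camera in limma on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, which compares a list with all other tested genes, and p-values were adjusted over the 46 lists. Camera with an estimated correlation was an alternative, and so was fry, which tests a list against no change and thus another hypothesis than camera. With an estimated correlation camera takes its degrees of freedom from the 4 libraries alone, so almost no list can pass after adjustment. For the list of nuclear respiratory chain genes the estimate was 0.02, near the preset, yet the camera p went from 1.37e-16 to 0.0176. A call lost in this alternative therefore says little for or against a list. Member counts come from the gene-wise limma test, adjusted over all genes and again over the list alone. Genes are named by a rule fixed at the same time. It takes the 3 IQGAP genes, and the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in the higher group, separated groups and an assigned gene name. It adds the 3 most changed called members of each primary list, the 2 most changed called members of each other list that passed its test or had at least 25% of its tested members called, and all 5 sex-specific genes. The rule gave 101 genes, and any other gene named was chosen after its values were seen.

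The alternatives fixed in advance were DESeq2 size factors, upper-quartile scaling, TMM with library sizes taken without the 20 most abundant genes, no low-count filter, a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, DESeq2, limma-voom, non-robust moderation, a test against a fold change of 1.5, and the 500 most variable genes for the principal components. The deposited scaling as it stands, edgeR on the recovered reads, a pseudocount of 25 and a crossed replicate block were added after the data were seen. With 1 mouse left out, the lone mouse of its group was assumed to vary like the pair in the other group. No sample was left out of the main comparison. Outlier tests and counts over other splits of the samples were not made, since they need larger groups.

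The procedure was tested on simulated counts drawn from the means and library sizes of the same 18285 genes. At a simulated fold change of 2, limma recovered 83 of 98 tested changed genes (84.7%), and at a fold change of 4 it recovered 92 of 97 (94.8%). It called 4 of 17398 unchanged genes. Camera called the list that had been raised and 0 of 20 unchanged lists. Simulated genes varied independently, so this cannot show how often camera calls lists of genes that move together. The mitosis list, for example, had an estimated inter-gene correlation of 0.853. The simulation also changed far fewer genes than were called in the data, with a spread set by the mean alone. Its rate of false calls therefore need not hold for the data. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used.

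Reads that overlap 2 genes, or fit near-identical copies, can be assigned to either, to both or to neither. The counting rule is not given in the sources used here. Tff1 and Gm15318 lie on opposite strands and had almost equal counts, 1049661 and 1049635 reads in vehicle replicate 1, so reads of the locus were counted for both. Levels of Try10, Uhrf1, Hbb-bt, Hspa1b, Hspb1, mt-Co3 and several other mitochondrial genes, which have near-identical copies, are uncertain. The same holds for Apoa4, Acadvl and Notum, whose exons overlap a gene on the opposite strand. mt-Co3 held 2083 reads over the 4 libraries together, against 816975 for mt-Nd2, for which no copy was found. Most reads of mt-Co3 may thus have been counted for no gene, while mt-Co1, which has 2 copies, held 2854421 reads.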

Results

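The series compared the transcriptome of the stomach corpus of mice 48 hr after HDT with that of vehicle mice, with 2 mice in each group. Its title concerns Iqgap3, an IQ-motif scaffold protein, and Ras in the division of corpus stem cells, and HDT was given to injure the tissue. Depth ranged from 41536686 to 42674985 recovered reads per library. At least 10 reads were found for 17720 and 17616 genes in vehicle replicates 1 and 2, and for 18534 and 18374 genes in HDT replicates 1 and 2. Across genes, log2 CPM correlated at 0.992 between the vehicle libraries, at 0.993 between the HDT libraries and at 0.967 to 0.969 between groups, and genes are not independent replicates. The first principal component held 78.5% of the variance and separated the groups. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 15.4 for the vehicle pair and 30.3 for the HDT pair. A gene's part in this value grows with its reads, so the most abundant genes weigh most. The value thus does not rank the pairs by their spread over all genes.

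At 48 hr after HDT, 14 of 18 genes of acid-secreting parietal cells were lower and 1 was higher. Of 11 genes of enzyme-secreting chief cells, 5 were lower and 1 was higher, and 40 of 40 mitosis genes were higher. All 3 lists were called, and none was with an estimated correlation (adjusted p = 0.582 for parietal cells and mitosis and adjusted p = 0.777 for chief cells). With 4 libraries that alternative has little power to call any list. The proton pump subunit Atp4b was at 4851 ± 177 CPM in vehicle and 529 ± 49.0 CPM in HDT (SD, n = 2), and the mitotic topoisomerase Top2a was at 32.4 ± 5.15 and 149 ± 20.5 CPM. Iqgap3 was at 6.31 ± 1.05 CPM in vehicle and 27.7 ± 4.88 CPM in HDT. All 34 nuclear genes of the respiratory chain and all 13 genes of mitochondrial DNA were lower. Among 22 fibroblast and matrix genes 16 were higher and 1 was lower, and 13 of 19 macrophage and monocyte genes were higher and 1 was lower. These 4 list calls too were lost with an estimated correlation (adjusted p = 0.582 for each). Of 18285 genes tested with limma, 3370 were higher and 3521 lower in HDT, 37.7% of the genes tested, and 745 of the rises and 823 of the falls were at least 2-fold. Both HDT libraries lay on the same side of both vehicle libraries for 70.8% of the genes, where chance gives 33.3%. edgeR on the recovered reads called 3358 higher and 3510 lower, and 6840 calls were shared with limma in the same direction.

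The direction of modest changes depends on the scaling. Used as deposited, the values gave 11483 genes higher and 998 lower, so 92% of the calls were rises against 48.9% with TMM. The deposited scaling raised the median log2 fold change of all tested genes to 0.526, from −0.001 with TMM, and changes are given here relative to the TMM median. camera compares a list with all other genes, so at the deposited scaling a list can be called lower while most of its called members are higher. It works on t-statistics, which the common shift raises more for precisely measured genes than for noisy ones. List calls made only at the deposited scaling are therefore not separate evidence of a fall relative to other genes. The most abundant genes moved with the groups. Pgc, the pepsinogen precursor of chief cells, took 12.9 ± 1.55% of all reads in vehicle and 4.14 ± 0.983% in HDT, and the 20 most abundant genes took 41.8 ± 1.48% and 22.2 ± 0.212% (SD, n = 2).

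**Figure D1:**
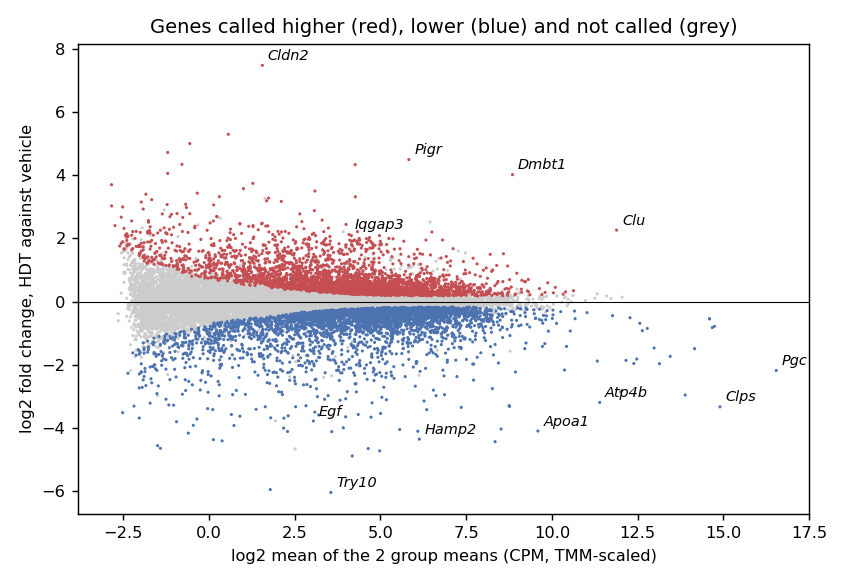
Log2 fold change of HDT against vehicle (vertical axis) against the log2 mean of both group means in CPM (horizontal axis) for 18285 tested genes, each point a gene. Red points are the 3370 genes called higher and blue points the 3521 called lower by limma, and labels mark genes of the text, from Cldn2 at 7.49 to Try10 at −6.05. At the deposited scaling the median of all genes lies 0.526 above its place here.

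Cell cycle genes rose together. All 40 members of the list of mitosis genes were higher in HDT, also when adjusted over the list alone, with a median log2 fold change of 1.82 (camera adjusted p = 7.67e-21, and adjusted p = 0.582 with an estimated correlation). The spindle checkpoint kinase Bub1b went from 7.07 ± 0.76 to 33.1 ± 5.56 CPM, the log2 fold change of Top2a was 2.21 and that of the checkpoint kinase Ttk was 2.13. Of 34 DNA replication genes, 33 were higher, and 34 adjusted over the list alone, with a median of 1.5 (camera adjusted p = 1.87e-16, and adjusted p = 0.582 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 rose by 2.09 on the log2 scale, the exonuclease Exo1 by 1.96 and the DNA methylation cofactor Uhrf1 by 1.90. Among the 3 IQGAP genes, Iqgap3, on chromosome 3 at 88081971 to 88121048 (GRCm38), rose by 2.13 on the log2 scale (SE 0.159, limma adjusted p = 0.000114). Iqgap1, on chromosome 7 at 80711583 to 80825974, was at 181 ± 2.73 and 198 ± 0.79 CPM (limma adjusted p = 0.116). Iqgap2, on chromosome 13 at 95627177 to 95891922, was at 244 ± 4.90 and 245 ± 2.77 CPM (limma adjusted p = 0.947). The family count of 1 of 3 higher, also adjusted over the list alone, gave no list call (camera adjusted p = 0.256, and called higher with fry at adjusted p = 0.0166). At the deposited scaling Iqgap1 and Iqgap2 were also called higher, by 0.66 and 0.54.

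**Figure D2:**
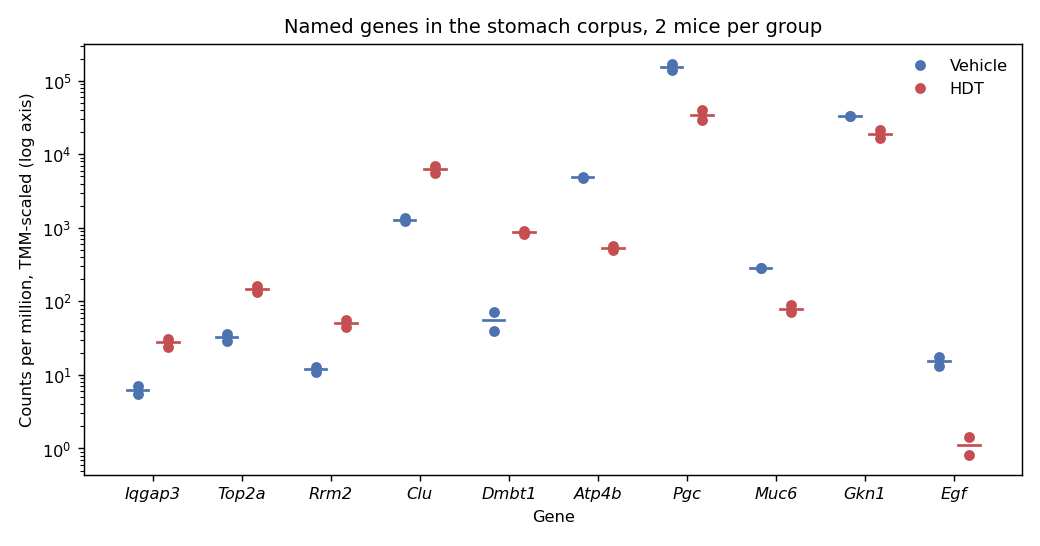
CPM on a log axis of 10 genes in each vehicle mouse (blue) and each HDT mouse (red), with a horizontal line at the mean of the 2 mice. Iqgap3, Top2a, Rrm2, Clu and Dmbt1 were higher in both HDT mice, and Atp4b, Pgc, Muc6, Gkn1 and Egf lower, and at the deposited scaling Gkn1 was not called.

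Most parietal cell genes fell. Of 18 tested members, 14 were lower, 1 was higher and 3 had no call, or 15 lower and 2 higher adjusted over the list alone, with a median of −1.46 (camera adjusted p = 1.2e-06, and adjusted p = 0.582 with an estimated correlation). The anion exchanger Slc26a7 fell by 3.66 on the log2 scale, Atp4b by 3.20 and the water channel Aqp4 by 3.08. The member called higher, the sodium-proton exchanger Slc9a4, had a log2 fold change of 0.26. Without vehicle replicate 1 or without vehicle replicate 2 it was no longer called, and the count of higher members was 0, and without HDT replicate 1 it was 2. Of 11 chief cell genes, 5 were lower, 1 was higher and 5 had no call, or 7 lower and 1 higher adjusted over the list alone, with a median of −1.5 (camera adjusted p = 0.0167, adjusted p = 0.777 with an estimated correlation and adjusted p = 0.0547 with fry). The pepsinogen gene Pga5 went from 175 ± 3.47 to 22.2 ± 2.54 CPM, Pgc fell by 2.19 on the log2 scale and Gif, which encodes intrinsic factor, by 2.17. With no low-count filter Gif was not called (limma adjusted p = 0.0592) and 3 chief cell genes were lower. The member called higher was Tnfrsf19, which is also in the list of stem cell markers. At the deposited scaling 3 chief cell genes were higher and 4 lower, with a median of −0.97. There 3 parietal cell genes were higher and 10 lower, with a median of −0.93.

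Of 13 tested genes of surface mucous, or pit, cells, 8 were lower, 3 higher and 2 without a call, the same counts as adjusted over the list alone, with a median of −0.55 (camera adjusted p = 0.0589). Dpcr1 went from 8322 ± 215 to 4396 ± 440 CPM, Psca from 9035 ± 244 to 5014 ± 520 CPM and the gastrokine Gkn1 from 33326 ± 549 to 18949 ± 3325 CPM. Without vehicle replicate 1 the count of lower pit cell genes was 3 and without vehicle replicate 2 it was 4, and the higher members numbered 1 in each case. The list was called lower with the replicate block (camera adjusted p = 0.045), with upper-quartile scaling (0.0467), with no low-count filter (0.0201), at the deposited scaling (0.00521), without vehicle replicate 2 (0.0482) and without HDT replicate 2 (0.00843). Gkn1 was not called without vehicle replicate 1 (limma adjusted p = 0.0712), without vehicle replicate 2 (0.0608) or at the deposited scaling (0.0801), where 2 pit cell genes were lower and 4 higher. Of 7 mucous neck cell genes, 3 were lower, 1 was higher and 3 had no call, or 3 lower and 2 higher adjusted over the list alone, with a median of −0.09, which was 0.44 at the deposited scaling, with 4 higher and 3 lower (camera adjusted p = 0.549). The gland mucin Muc6 went from 284 ± 3.82 to 79.96 ± 11.99 CPM and the glycosyltransferase gene B4galnt3 from 81.8 ± 7.71 to 30.3 ± 1.76 CPM, while the chloride channel Cftr rose from 0.30 ± 0.14 to 3.70 ± 0.85 CPM. Without vehicle replicate 1 or without vehicle replicate 2 the count of higher neck cell genes was 2. This list was called lower with fry (adjusted p = 0.0166) and at the deposited scaling (camera adjusted p = 0.024).

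Of 17 endocrine cell genes, 3 were lower, 1 was higher and 13 had no call, as also adjusted over the list alone, with a median of −0.37 that was 0.15 at the deposited scaling, with 2 higher and 2 lower (camera adjusted p = 0.256). Somatostatin (Sst) fell from 333 ± 9.34 to 176 ± 3.30 CPM and ghrelin (Ghrl) from 832 ± 33.3 to 476 ± 43.7 CPM, and the decarboxylase Ddc rose by 0.58 on the log2 scale. Without HDT replicate 1 the counts were 7 lower and 2 higher and the list was called lower (camera adjusted p = 0.0163), as at the deposited scaling (0.014). Without HDT replicate 2 the higher members numbered 6.

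Genes described in spasmolytic polypeptide-expressing metaplasia (SPEM) and gastric injury moved both ways. Of 28 tested, 12 were higher, 5 lower and 11 without a call, or 12 higher and 6 lower adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.0406, and adjusted p = 0.582 with an estimated correlation). The secreted scavenger receptor Dmbt1 went from 55.6 ± 23.0 to 867 ± 59.6 CPM, Cftr rose by 3.58 on the log2 scale and the tight junction gene Cldn4 by 3.08. Clu, chosen after its values were seen, went from 1297 ± 83.7 to 6261 ± 876 CPM. The mucous genes Muc6 and Tff2, which the neck cell list also holds, were among the lower members. The list call was lost without HDT replicate 1 (camera adjusted p = 0.0751), without HDT replicate 2 (0.123), with upper-quartile scaling (0.0599) and at the deposited scaling (0.832), and without HDT replicate 1 the lower members numbered 3.

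**Figure D3:**
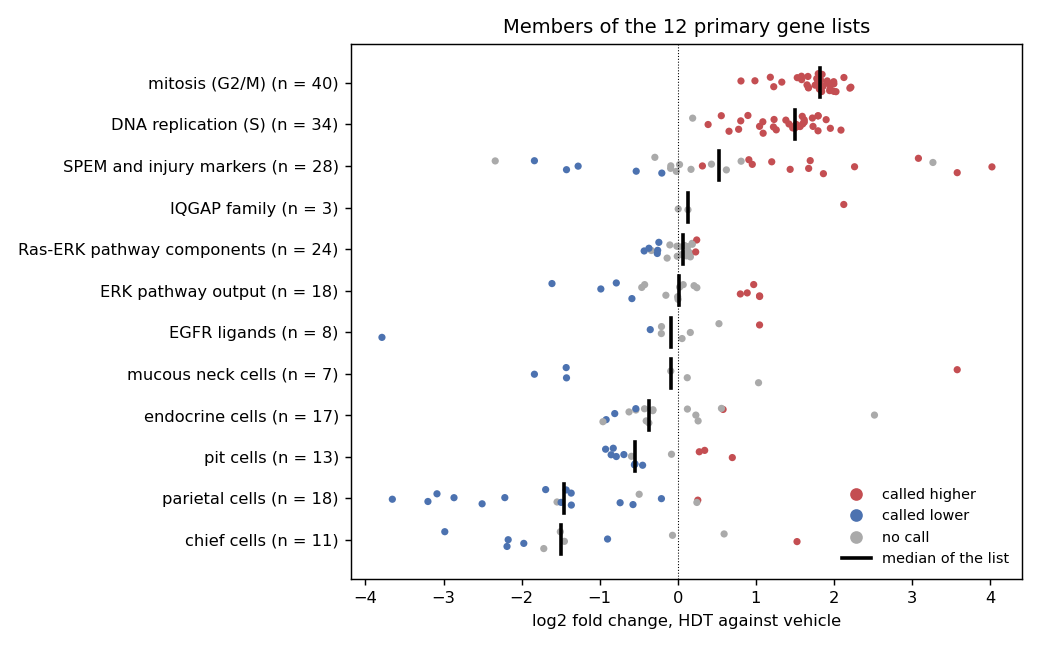
Log2 fold change of HDT against vehicle (horizontal axis) for the tested members of the 12 primary gene lists (vertical axis), each point a gene coloured by its limma call, with a black bar at the list median. Medians run from −1.5 for chief cells to 1.82 for mitosis. At the deposited scaling the medians of mucous neck cells, endocrine cells and EGFR ligands lie above 0, at 0.44, 0.15 and 0.45.

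The 5 largest rises under the naming rule were those of the tight junction gene Cldn2 (chromosome X, 139800828 to 139811386), the immunoglobulin transporter gene Pigr (chromosome 1, 130826684 to 130852249), the phagocyte glycoprotein gene Gpnmb (chromosome 6, 49036546 to 49070929), Dmbt1 (chromosome 7, 131032053 to 131121630) and the macrophage elastase gene Mmp12 (chromosome 9, 7344381 to 7369499). Cldn2 had 1 read in the vehicle libraries and 596 in the HDT libraries, a ratio of 407 with an exact 95% counting interval of 72.8 to 16100. The interval pools the 2 mice of a group and covers counting error only, and replicates varied by more than that. The log2 fold change was 4.5 for Pigr, 4.34 for Gpnmb, 4.03 for Dmbt1 and 3.32 for Mmp12. Some of these calls were lost with 3 mice, at similar folds. Pigr was not called without HDT replicate 1 (log2 fold change 4.306, limma adjusted p = 0.19), without HDT replicate 2 (4.718, 0.147) or with no low-count filter (4.515, 0.0574), nor Dmbt1 without HDT replicate 1 (3.961, 0.166) or HDT replicate 2 (4.111, 0.142). Mmp12 was not called without vehicle replicate 1 (3.144, 0.0751) or vehicle replicate 2 (3.491, 0.0723), nor Gpnmb without vehicle replicate 2 (4.485, 0.0501). The 5 largest falls were those of the trypsin gene Try10 (chromosome 6, 41354105 to 41357914), D7Ertd443e (chromosome 7, 134265779 to 134385661), the dehydrogenase gene Sdr9c7 (chromosome 10, 127898518 to 127911761), the ribonuclease gene Rnase1 (chromosome 14, 51144998 to 51146785) and the hepcidin gene Hamp2 (chromosome 7, 30922372 to 30924681). Try10, which has a near-identical copy, went from 23.1 ± 1.05 to 0.34 ± 0.15 CPM, and Hamp2 from 134 ± 7.08 to 6.48 ± 0.06 CPM. The log2 fold change was −6.05 for Try10, −5.96 for D7Ertd443e, −4.90 for Sdr9c7, −4.74 for Rnase1 and −4.36 for Hamp2. All positions are those of whole protein-coding genes in GENCODE M21.

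Targets used as a readout of ERK signalling moved both ways. Of 18 tested, 5 were higher, 4 lower and 9 without a call, or 6 higher and 4 lower adjusted over the list alone, with a median of 0.01 (camera adjusted p = 0.827), and at the deposited scaling 12 were higher. The ERK phosphatase gene Dusp6 fell from 49.4 ± 4.62 to 16.1 ± 1.15 CPM, while Myc rose from 17.8 ± 0.84 to 36.8 ± 2.7 CPM and the transcription factor Etv4 from 2.31 ± 0.02 to 4.82 ± 0.48 CPM. Of 24 genes of the Ras-ERK cascade itself, 5 were lower, 2 higher and 17 without a call, as also adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.827). Hras, Sos2 and Ptpn11 had log2 fold changes of −0.43, −0.37 and −0.26 with TMM and of 0.10, 0.16 and 0.27 at the deposited scaling, where 21 members were called higher and 0 lower. Without vehicle replicate 1 the cascade had 2 lower and 0 higher members and without vehicle replicate 2 it had 3 and 0, and the higher members numbered 5 without HDT replicate 1 and 1 without HDT replicate 2. Ptpn11 was not called without vehicle replicate 1 (limma adjusted p = 0.0528) or vehicle replicate 2 (0.0644).

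Of 8 tested ligands of the EGF receptor family, 2 were lower, 1 was higher and 5 had no call, as also adjusted over the list alone, with a median of −0.08 that was 0.45 at the deposited scaling, with 5 higher and 1 lower (camera adjusted p = 0.827). Egf went from 15.4 ± 2.84 to 1.13 ± 0.44 CPM, a log2 fold change of −3.79. Nrg1 rose from 4.31 ± 0.30 to 8.93 ± 0.60 CPM. Tgfa, at 56.3 ± 0.83 and 44.2 ± 5.64 CPM, had a log2 fold change of −0.35 that was 0.18 at the deposited scaling, and it was not called without HDT replicate 1 (limma adjusted p = 0.0567), which left 1 lower member. Without vehicle replicate 1 the higher members numbered 2.

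Markers of gastric stem and progenitor cells were higher as a list. Of 14 tested, 8 were higher, 1 was lower and 5 had no call, or 10 higher and 2 lower adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.0109, and adjusted p = 0.687 with an estimated correlation). Iqgap3 is a member, as is Tnfrsf19, which went from 7.15 ± 0.25 to 20.9 ± 4.55 CPM. The stem and progenitor list shares Stmn1 with the mitosis list and Cd44, Sox9 and Olfm4 with the SPEM list. It also shares Axin2 and Lgr5 with the Wnt and Notch list, and Lgr5, Tnfrsf19 and Bhlha15 with the chief cell list. Its call is therefore not independent of theirs. The call was lost at the deposited scaling (camera adjusted p = 0.194), fry, which tests against no change, gave adjusted p = 0.084, and without HDT replicate 1 or without HDT replicate 2 the lower members numbered 2. Of 18 Wnt and Notch targets, 9 were higher and 9 without a call, or 9 higher and 1 lower adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.0129, and adjusted p = 0.582 with an estimated correlation). The Wnt target Ascl2 rose from 0.33 ± 0.15 to 4.51 ± 0.04 CPM and Notum from 0.14 ± 0.08 to 0.68 ± 0.05 CPM. Notum was not called without HDT replicate 1 (limma adjusted p = 0.0531) or HDT replicate 2 (0.0726), and the list call was lost at the deposited scaling (camera adjusted p = 0.0748).

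The 4 lists of energy metabolism genes were called lower with TMM. All 34 nuclear-encoded subunits of the respiratory chain and ATP synthase fell, also adjusted over the list alone, with a median of −0.75 (camera adjusted p = 2.09e-15, and adjusted p = 0.582 with an estimated correlation). At the deposited scaling 21 of them were lower and 1 was higher. Ndufa1 went from 61.2 ± 0.30 to 19.4 ± 0.06 CPM and Uqcrq from 231 ± 8.26 to 84.7 ± 2.89 CPM. All 13 protein-coding genes of mitochondrial DNA fell, also adjusted over the list alone, with a median of −1.82 (camera adjusted p = 8.64e-10, and adjusted p = 0.582 with an estimated correlation). mt-Nd2 fell by 1.97 on the log2 scale and mt-Co3, which has a near-identical nuclear copy, by 2.07. Of 20 fatty acid oxidation genes, 12 were lower, 1 was higher and 7 had no call, or 12 lower and 2 higher adjusted over the list alone, with a median of −0.29 that was 0.24 at the deposited scaling, where 12 were higher and 3 lower and the list call was lost (camera adjusted p = 0.00573 with TMM and 0.132 as deposited, and adjusted p = 0.582 with an estimated correlation). Acadm fell by 1.10 and Acadvl by 0.80 on the log2 scale, and without HDT replicate 1 the higher members numbered 2. Of 15 glycolysis genes, 12 were lower and 3 without a call, or 13 lower adjusted over the list alone, with a median of −0.44 that was 0.10 at the deposited scaling, with 5 higher and 4 lower (camera adjusted p = 8.48e-05, and adjusted p = 0.582 with an estimated correlation). The regulatory kinase Pfkfb3 fell by 2.34 and Pfkl by 0.98 on the log2 scale.

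Stress pathways moved in different directions. Of 19 NRF2 targets, genes of the oxidative stress response, 12 were higher, 1 was lower and 6 had no call, or 13 higher and 1 lower adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.000453, adjusted p = 0.687 with an estimated correlation and adjusted p = 0.0623 with fry). The glutathione peroxidase Gpx2 rose from 66.2 ± 3.36 to 212 ± 6.04 CPM and the cystine transporter Slc7a11 by 1.44 on the log2 scale. Both are also in the SPEM list, and without HDT replicate 2 the lower members numbered 2. Of 21 genes of the unfolded protein response, 15 were lower and 6 without a call, or 16 lower and 1 higher adjusted over the list alone, with a median of −0.63 (camera adjusted p = 1.31e-05, and adjusted p = 0.582 with an estimated correlation). Creld2 fell by 1.17 and Chac1 by 1.15 on the log2 scale. At the deposited scaling 6 members were lower and 5 higher, and without vehicle replicate 1 or without HDT replicate 2 the higher members numbered 1. Of 12 glucocorticoid targets, 7 were lower and 5 without a call, as also adjusted over the list alone, with a median of −0.49 that was 0.04 at the deposited scaling, with 3 higher and 1 lower (camera adjusted p = 0.03, and adjusted p = 0.582 with an estimated correlation). Sgk1 fell by 1.28 and Lcn2 by 1.28 on the log2 scale. The list call was lost without vehicle replicate 1 (camera adjusted p = 0.0652), and Lcn2 was not called without vehicle replicate 1 (limma adjusted p = 0.143), without HDT replicate 1 (0.16), at the deposited scaling (0.112) or with DESeq2 (0.0595).

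Genes of stromal and immune cells were measured as cell types the tissue also holds. Of 22 fibroblast and matrix genes, 16 were higher, 1 was lower and 5 had no call, or 18 higher and 1 lower adjusted over the list alone, with a median of 0.87 (camera adjusted p = 4.28e-06, and adjusted p = 0.582 with an estimated correlation). The collagen Col1a1 went from 198 ± 2.13 to 570 ± 76.9 CPM and Col5a1 from 39.2 ± 0.47 to 111 ± 7.81 CPM. Of 19 macrophage and monocyte genes, 13 were higher, 1 was lower and 5 had no call, as also adjusted over the list alone, with a median of 0.64 (camera adjusted p = 5.3e-05, and adjusted p = 0.582 with an estimated correlation). The lysosomal glycoprotein Cd68 rose from 10.4 ± 1.04 to 38.1 ± 1.53 CPM, while the monocyte marker Ly6c2 fell from 1.69 ± 0.05 to 0.57 ± 0.15 CPM. The 22 interferon response genes were higher as a list, with a median of 0.87 (camera adjusted p = 0.00418, adjusted p = 0.847 with an estimated correlation and adjusted p = 0.412 with fry), although 1 was called, Psmb8, and none adjusted over the list alone. By unadjusted p, 2 members were higher, and edgeR called 1 and DESeq2 2. All 22 genes were lowest in vehicle replicate 2, and 20 were highest in HDT replicate 2. The list call was lost without vehicle replicate 2 (camera adjusted p = 0.0715), without HDT replicate 2 (0.0755) and at the deposited scaling (0.612), and the members called numbered 8 without vehicle replicate 1, 2 without HDT replicate 1 and 0 without vehicle replicate 2 or HDT replicate 2. Psmb8, at 8.68 ± 1.43 and 13.9 ± 3.36 CPM, was not called without vehicle replicate 2 (limma adjusted p = 0.151) or HDT replicate 2 (0.105).

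The main fit made no list call for other immune and stromal cells. Neutrophil genes had 2 higher and 2 lower of 8 tested, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.886), with S100a9 lower by a log2 fold change of −2.53 and Mmp8 higher by 2.52. T and NK cell genes had 1 higher and 2 lower of 6, as also adjusted over the list alone (camera adjusted p = 0.805), with Cd4 at 1.17 and Trbc2 at −1.74. B and plasma cell genes had 2 higher and 2 lower of 9, as also adjusted over the list alone (camera adjusted p = 0.827). Derl3, a gene of endoplasmic reticulum degradation, fell from 28.5 ± 3.10 to 1.75 ± 0.05 CPM, and the B cell coactivator Pou2af1 rose by 2.7 on the log2 scale. Mast cell and eosinophil genes had 0 higher and 2 lower of 12, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.137). Inflammatory cytokines had 1 higher and 2 lower of 14, as also adjusted over the list alone (camera adjusted p = 0.728). Endothelial genes had 0 higher and 6 lower of 14, as also adjusted over the list alone (camera adjusted p = 0.549), with Cldn5 at −0.91 and Kdr at −0.64, and at the deposited scaling 7 were higher and 0 lower. Smooth muscle genes had no call among 12, also adjusted over the list alone (camera adjusted p = 0.549), 1 lower by unadjusted p, 0 calls with edgeR and 1 with DESeq2. Neuronal and glial genes had 1 higher and 2 lower of 13, as also adjusted over the list alone (camera adjusted p = 0.349). As deposited, the higher and lower members numbered 4 and 2 among neutrophil, 1 and 1 among T and NK cell, 2 and 1 among B and plasma cell, 1 and 1 among mast cell, 6 and 0 among cytokine, 1 and 0 among smooth muscle and 3 and 0 among neuronal and glial genes. Several of these counts changed when a library was left out. Without vehicle replicate 2 the lower mast cell members numbered 7, and without HDT replicate 2 they numbered 1. The mast cell list was called lower without vehicle replicate 2 (camera adjusted p = 0.00705), with a filter of 1 CPM in 2 libraries (0.0397) and at the deposited scaling (0.000683), where B and plasma cells were called lower as well (0.0492). Endothelial genes had 2 higher and 2 lower without vehicle replicate 2 and 2 lower without HDT replicate 2, and 1 smooth muscle gene was lower without vehicle replicate 2. The higher neutrophil members numbered 4 without HDT replicate 2 and 1 without HDT replicate 1, where 3 were lower. T and NK cells had no lower gene without vehicle replicate 2 or HDT replicate 1 and 1 without vehicle replicate 1 or HDT replicate 2, and 2 were higher without vehicle replicate 2. Cytokines had 2 higher and 3 lower without vehicle replicate 2, 0 higher without HDT replicate 2 and 1 lower without vehicle replicate 1. Neuronal and glial genes had 0 higher and 4 lower without HDT replicate 2, 3 lower without vehicle replicate 2 and 1 lower without vehicle replicate 1 or HDT replicate 1. Mmp8 was not called without HDT replicate 1 (limma adjusted p = 0.243), Trbc2 not without vehicle replicate 2 (0.0707) or HDT replicate 1 (0.097), and Cldn5 not without vehicle replicate 2 (0.242), HDT replicate 1 (0.146) or HDT replicate 2 (0.102), and neither Cldn5 (0.237) nor Kdr (0.376) was called at the deposited scaling.

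Lists of exocrine, fat, blood and neighbouring tissue were also measured. Exocrine pancreas genes had 2 lower of 7 tested, or 1 lower adjusted over the list alone, with a median of −2.35 (camera adjusted p = 0.0129, adjusted p = 0.752 with an estimated correlation and adjusted p = 0.0944 with fry). DESeq2 called 5 of the 7 lower and edgeR 1. Clps, the colipase gene, went from 55486 ± 7302 to 5530 ± 1294 CPM, and in vehicle replicate 1, where acinar genes were scarce, it was at 50323 CPM. Pnliprp1 had a log2 fold change of −1.97 and was not called when any of the 4 libraries was left out (limma adjusted p from 0.0952 without HDT replicate 1 to 0.212 without vehicle replicate 2), nor with edgeR (0.0507), no low-count filter (0.115) or the deposited scaling (0.0713). Acinar enzyme genes stood apart in vehicle replicate 2, at a summed 204.5 CPM over 10 genes against 18.0 CPM in vehicle replicate 1, 8.60 CPM in HDT replicate 1 and 7.40 CPM in HDT replicate 2. With vehicle replicate 2 kept and another library left out, 13 pancreas genes were tested, against 7 without vehicle replicate 2. Counts of lower members are therefore not compared across these fits. Of 9 adipocyte genes, 4 were lower and 5 without a call, as also adjusted over the list alone, with a median of −0.70 (camera adjusted p = 0.0129, and adjusted p = 0.582 with an estimated correlation). Lpl went from 535 ± 36.1 to 79.1 ± 9.73 CPM and Plin4 fell by 1.51 on the log2 scale, and the list call was lost without HDT replicate 2 (camera adjusted p = 0.0611). All 6 tested red blood cell genes fell, also adjusted over the list alone, with a median of −1.94 (camera adjusted p = 0.00227, and adjusted p = 0.624 with an estimated correlation), among them Hbb-bs by 2.26 and Hbb-bt by 2.48 on the log2 scale. Antrum and duodenum genes had 2 higher and 2 lower of 9, as also adjusted over the list alone (camera adjusted p = 0.616). The list was called lower with fry (adjusted p = 0.0102) and at the deposited scaling (camera adjusted p = 0.0415), with 1 higher member without vehicle replicate 1 and 1 higher and 3 lower without HDT replicate 2. The apolipoprotein genes Apoa1 and Apoa4 both fell by 4.11 on the log2 scale. Squamous forestomach genes had 1 higher and 1 lower of 10, as also adjusted over the list alone (camera adjusted p = 0.596), and without vehicle replicate 2 the counts were 3 and 2, while without vehicle replicate 1 or HDT replicate 2 none was lower. As deposited, 4 antrum and duodenum genes were higher and 2 lower, and 5 squamous genes were higher and 0 lower.

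The remaining pathway lists had no list call in the main fit. The p53 targets had 8 higher and 3 lower of 18, as also adjusted over the list alone, and 15 and 1 at the deposited scaling (camera adjusted p = 0.109). The higher members numbered 5 without vehicle replicate 2 or HDT replicate 1, the lower members 1 without vehicle replicate 2, and without HDT replicate 2 the list was called higher (camera adjusted p = 0.0317). Ddit4l rose by 1.23 on the log2 scale and the cell cycle inhibitor Cdkn1a fell from 350 ± 32.4 to 175 ± 18.4 CPM. Cholesterol synthesis genes had 3 higher and 2 lower of 24, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.728), with 19 higher and 0 lower at the deposited scaling. The lower members numbered 8 without HDT replicate 2 and 1 without vehicle replicate 2 or HDT replicate 1, and 5 were higher without HDT replicate 1. Xenobiotic metabolism genes had 4 higher and 3 lower of 16, or 5 and 3 adjusted over the list alone and 10 and 0 at the deposited scaling (camera adjusted p = 0.895, and called higher with fry at adjusted p = 0.0333), with 7 lower without HDT replicate 2. Cyp2c55 went from 1.91 ± 0.13 to 11.2 ± 0.41 CPM, and the transporter gene Abcc2 had 2 reads in vehicle and 47 in HDT, a ratio of 16.1 with an exact 95% counting interval of 4.21 to 137, which likewise pools the mice and covers counting error only. Abcc2 was not called without HDT replicate 1 (limma adjusted p = 0.15). Oestrogen receptor targets had 3 higher and 4 lower of 15, or 4 and 4 adjusted over the list alone and 7 and 2 at the deposited scaling (camera adjusted p = 0.719), with Ltf at a log2 fold change of 2.19 and C3 at −1.18. C3 was not called without HDT replicate 1 (limma adjusted p = 0.143) or HDT replicate 2 (0.0832). YAP targets had 4 higher and 5 lower of 13, or 4 and 6 adjusted over the list alone and 5 and 3 at the deposited scaling (camera adjusted p = 0.31, and called lower with fry at adjusted p = 0.0292), with Nt5e at −0.92 and Amotl2 at −0.74. Immediate early genes had 2 higher and 7 lower of 18, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.161), and at the deposited scaling 9 higher and 1 lower with a median of 0.31, against −0.22 with TMM. Klf2 had a log2 fold change of −0.94 and Egr2 of 1.20. The higher members numbered 4 without vehicle replicate 1 and 1 without HDT replicate 2. Without vehicle replicate 2 this list was called lower (camera adjusted p = 0.00575), and Egr2 was not called without HDT replicate 2 (limma adjusted p = 0.0561). Heat shock genes had 2 higher and 2 lower of 11, as also adjusted over the list alone, and 9 and 0 at the deposited scaling (camera adjusted p = 0.719), with Hspa1b at 0.74 and Hspb1 at −0.70, both of which have near-identical copies. Without vehicle replicate 1 or HDT replicate 1 the counts were 3 and 1, and without HDT replicate 2 they were 2 and 3. Hspb1 was not called without vehicle replicate 1 (limma adjusted p = 0.0834), without HDT replicate 1 (0.142), with no low-count filter (0.0767), with upper-quartile scaling (0.0548) or at the deposited scaling (0.512). Circadian clock genes had 2 higher and 8 lower of 14, as also adjusted over the list alone (camera adjusted p = 0.0594), and at the deposited scaling 5 higher and 2 lower with a median of 0.05, against −0.46 with TMM. Tef had a log2 fold change of −1.36 and Hlf of −1.06. The list was called lower with the replicate block (camera adjusted p = 0.0389), with no low-count filter (0.0201), at the deposited scaling (0.014), without vehicle replicate 2 (0.0215), without HDT replicate 1 (0.0488) and with fry (adjusted p = 0.0166). It had 1 higher member without vehicle replicate 1.

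Sex-specific genes had no list call (camera adjusted p = 0.827). Xist was at 0.17 to 0.37 CPM in all 4 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 14.6 to 37.9 CPM in all 4. Ddx3y was lower in HDT with TMM, with a log2 fold change of −0.41, and at 0.12 at the deposited scaling, where 3 members were higher and 0 lower. With TMM the call of Ddx3y was also the only call adjusted over the list alone. Kdm5d was called higher without vehicle replicate 2, with a log2 fold change of 0.36 (limma adjusted p = 0.0309).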

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

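The deposited scaling, edgeR on recovered reads, the pseudocount of 25 and the crossed block were chosen after the data were seen. Under the other settings that keep all 4 libraries, apart from a test against a fold change of 1.5 that called 450 genes higher and 644 lower because small changes cannot pass it, the counts of changed genes stayed within 1.5 times of 3370 and 3521, and 0 of the 6891 calls turned to a call in the opposite direction. The deposited scaling is the exception, with 11483 higher, 998 lower and 715 calls turned. It also gave 2 lower pit cell genes, 12 higher ERK targets, 0 lower and 21 higher genes of the Ras-ERK cascade, 3 higher IQGAP genes, 1 lower EGFR ligand, and 5 lists higher and 17 lower, of which 15 were among the 20 calls made with TMM. Its log2 fold changes were opposite in sign for Hras (0.10), Sos2 (0.16), Ptpn11 (0.27), Tgfa (0.18), Ddx3y (0.12) and Eif2s3y (0.41), which its common shift of 0.526 accounts for. With an estimated inter-gene correlation camera called 0 lists higher and 0 lower, with 1 of 46 at an unadjusted p under 0.05. With the few degrees of freedom that 4 libraries give, almost no list could have passed there. By contrast fry, which tests against no change, called 21 lists and held 15 of the 20. With no low-count filter 3 chief cell genes were lower, and the cause was not tested. The 500 most variable genes gave a first component of 86.4%, since genes were picked for their variance.

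Leaving out each mouse gave 2538 to 2749 genes higher and 2773 to 3041 lower, and 8 to 9 lists higher and 10 to 15 lower. Lower members ranged from 3 to 9 for pit cells (3 without vehicle replicate 1, 4 without vehicle replicate 2), 3 to 7 for endocrine cells (7 without HDT replicate 1), 2 to 5 for the Ras-ERK cascade (2 without vehicle replicate 1, 3 without vehicle replicate 2) and 1 to 3 for EGFR ligands (1 without HDT replicate 1), where fewer samples enter the fit. Of 101 named genes, between 6 and 12 lost their call when a mouse was left out, and none with a call changed sign, while Xist and Iqgap2, which had none, did. No gene with fewer than 10 reads in its highest library was tested in the main fit, so its counts leave out changes there. Such genes entered the fit with no low-count filter, which tested 28906 genes.

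With the replicate number as a block, 2371 genes were higher and 2630 lower, 3 genes of the Ras-ERK cascade were lower, the 20 list calls were kept, pit cells (camera adjusted p = 0.045) and the circadian clock (0.0389) were also called lower, and Pnliprp1, Psmb8, Hspb1 and Lcn2 lost their calls. The numbers are not known to pair the mice: same-numbered libraries deviated in opposite directions, with a correlation of −0.155 across 18285 genes and of −0.442 across the 11454 genes over 5 CPM. A crossed block, vehicle replicate 1 with HDT replicate 2, gave 4200 higher and 4321 lower.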

Other observations

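The tests in this part on scaling, acinar tissue and parietal share, and the 5 gene lists added here, were chosen only after the gene and list results were seen. Genes of phagocytes that take up lipid and cell debris were followed up because Gpnmb and Mmp12 were among the largest rises. Both are members, so the list with them, of 17 tested with 8 higher and none lower, is not independent of that observation. Without them 6 of 15 were higher and none lower, with a median of 0.33 (camera adjusted p = 0.00411 over the 5 added lists, and adjusted p = 0.316 with an estimated correlation). The integrin gene Itgax had a log2 fold change of 2.58, the phagocyte receptor Trem2 2.02, osteopontin (Spp1) 1.5 and cathepsin S (Ctss) 1.00, while 9 members, among them Apoe and Ctsb, had no call. Cd68 is not a member of this list and was at 38.1 CPM in HDT against 10.4 CPM in vehicle.

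Genes of the Fanconi pathway and homologous recombination, which repair DNA during replication, rose beside the replication genes. Of 17 tested, 15 were higher and none lower, with a median of 0.84 (camera adjusted p = 4.35e-07 over the 5 added lists, and adjusted p = 0.316 with an estimated correlation), led by Fancd2 at 2.22 and Brca1 at 1.81. Cytosolic ribosomal protein genes, which growing cells need, had 11 higher and 6 lower of 48, with a median of 0.07 (camera adjusted p = 0.164). The endocrine granule gene Chgb was at 24.2 and 23.9 CPM in the vehicle libraries and at 210 CPM in HDT replicate 1 and 90.7 CPM in HDT replicate 2, and had no call (limma adjusted p = 0.0743). Interferon response genes had a median log2 CPM of 4.96 and 3.79 in vehicle replicates 1 and 2 and of 4.75 and 5.39 in HDT replicates 1 and 2.

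At the deposited scaling most called genes were higher in HDT. The shift may come from a few abundant genes: with totals taken without the 20 most abundant genes the median log2 fold change over tested genes was 0.114, against 0.526 as deposited. A rise in RNA per cell cannot be told apart from this, because the table has 0 rows of spike-in transcripts that would give an absolute scale. A loss of the most abundant secretory transcripts alone and a gain in all other transcripts would give the same table.

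Vehicle replicate 2 held transcripts of pancreatic acinar enzymes. Of 10 acinar genes, 9, or 90%, were over 5 times higher there than in vehicle replicate 1, and 3 of the 10, Cel, Cela2a and Ctrc, were above 1 CPM in the other libraries as well. Since 3 of the 10 genes had prompted this test, it restates what was seen, while of the 7 others 6, or 85.7%, passed the same bound, so acinar cells may be the source. Whether pancreas was carried along at dissection cannot be told apart from acinar cells in the stomach of that mouse, as both would give these transcripts. The strictly acinar list, with 4 tested genes, had no list call for HDT against vehicle (camera adjusted p = 0.124 over the 5 added lists), and acinar tissue in vehicle replicate 2 did not account for the fall of Clps and Pla2g1b, which without vehicle replicate 2 still had log2 fold changes of −3.21 and −2.821.

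The fall of all 34 nuclear respiratory chain genes was weighed against 3 explanations. A trend over all genes with transcript length, GC content or expression level did not account for the whole fall. The median was −0.748 before a spline fit on these and −0.488 after it, with an SD of 0.29 over members. The fit thus took up part of the fall, and the residual median lay below the lowest of 10000 random lists (−0.395). It explained 2.7% of the variance over genes and used the longest transcript of each gene. A bias limited to short transcripts is therefore not excluded. A fall of the same size in all nuclear genes for mitochondrial proteins was argued against. The 40 mitochondrial ribosomal protein genes had a median of −0.096, 0.652 above that of the chain (permutation p = 1e-05, the smallest that 100000 permutations can give). They still leaned lower, with 13 lower and 2 higher (camera adjusted p = 0.0476 over the 5 added lists, and adjusted p = 0.463 with an estimated correlation). Fatty acid oxidation genes, mitochondrial and peroxisomal, had 12 lower and 1 higher of 20, with a median of −0.29. A smaller general fall is therefore left open. A smaller share of RNA from parietal cells, which are rich in mitochondria, may contribute, but the test made here could not decide it. The parietal median lay at −0.714 relative to that of the chain (permutation p = 9e-05). Both medians were known when this test was chosen, and only a smaller parietal fall could have counted against this explanation. Whether the chain also fell within the remaining cells cannot be told apart from a smaller parietal share in whole tissue. Both permutation tests shuffled genes between lists, so their p-values treat genes as independent and measure no spread between mice.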
